A study of Mus musculus with 4 samples.

How the data were processed

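The comparisons, gene lists, tests and most alternatives were written down before the data were examined. The 4 samples were dissociated mammary tumours of FVB mice with the MMTV-PyMT transgene, 2 labelled 12 weeks and 2 labelled 15 weeks. The series design text gives the later age as 16 weeks, and the sample labels are followed here. Per the labels' protocols, tumours were minced and digested with collagenase I, dissociated mechanically and treated to lyse red blood cells, and cells were loaded on a droplet kit of version 2 chemistry, which counts 3' tags. The deposited values are UMI counts per gene and barcode, made with Cell Ranger 3.0.2 on mm10, per the submitters' processing notes. These notes also name Seurat 3.0.2 without its steps, and the counts are whole numbers in barcodes already called as cells. Nothing in the labels says whether the libraries came from separate animals.

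From these counts, cells with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were kept. Doublets were removed with scrublet in scanpy 1.11.5. Its automatic threshold marked under 0.5% of cells in 3 libraries (0.384%, 0.102% and 0.157%), and there the cells with the highest scores were removed up to 0.8% per 1000 cells. This removed 27 and 69 cells at 12 weeks and 13 and 23 cells at 15 weeks. Cells were clustered on log counts per 10000 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2). The variable genes left out mitochondrial genes, ribosomal protein genes and the tested lists, apart from list members that are also cell type markers. Clusters were named from 15 marker lists. A class needed at least 3 detected markers, a scaled level of 0.35 and a lead of 0.15 over the next class, and clusters without this stayed unnamed. Libraries were not aligned to each other before clustering. Names such as epithelial-like describe transcripts, and tumour and normal epithelium were not separated.

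Counts of each class were summed per library, for classes with at least 20 cells in every library, which left out T/NK cell-like, myoepithelial-like, pericyte-like and neutrophil-like cells from gene tests. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. Values are log2 fold changes ± SE, and CPM are counts scaled to the effective library size. Where an age was left with a single library, that library is assumed to vary like the others. Of 30 gene lists, those with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, which treats members as nearly independent, and again with a correlation estimated from the residuals. Members were also adjusted over their list alone. Shares of cells were compared with an exact two-sided permutation test, and intervals of single shares are exact binomial.

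For the hypoxia score, epithelial-like cells with at least 2000 UMIs were thinned to 2000, which left 1113 and 1861 cells at 12 weeks and 687 and 2363 at 15 weeks. The score is the mean of log2(1 + UMIs) over 39 of 40 listed hypoxia genes found in the files. The 25% of cells with the highest and with the lowest score in each library were summed, and the 8 sums were fitted with the library as a block and without the score genes. Epithelial-like and macrophage/monocyte-like sums were compared with the library as a block as well. Chromosome positions came from an annotation of GRCm38, the assembly also called mm10, in which 30934 of 31053 gene IDs were found, 30444 of them with the same symbol.

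Genes are named by a fixed rule. It takes up to 10 genes per direction with the largest change among those past the threshold whose libraries all lie on 1 side, or the 5 with the smallest p per direction where none passes. It adds list members with the highest expression or past the threshold, and in epithelial-like cells a set of interferon, antigen presentation and hypoxia genes. Haemoglobin and mitochondrial genes are passed over, and those in the text were named after their values were seen. Some genes that the rule names are not reported here.

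Each fit was tested on simulated data of the same design, with genes raised or lowered 2-fold, 4-fold or 8-fold. At 4-fold, edgeR called 73.1% of changed genes in macrophage/monocyte-like, 55.2% in fibroblast-like and 77.6% in endothelial-like cells, 100% for the hypoxia score, 65.7% for the interaction and 97.0% for epithelial-like against macrophage/monocyte-like cells. In epithelial-like cells 18 of 13150 unchanged genes were called. Alternatives covered DESeq2 1.42.0 with fry, another normalization, no low-count filter, each library left out, the replicate number as a block, thinned cells, equal cell numbers, genes of other classes left out, 2 other cell filters, no doublet removal, Leiden resolution 0.5, and other forms of the score. Leaving out clusters mostly of 1 library, a score of core hypoxia genes, and an estimated correlation for the score, interaction and class comparisons were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9 were used.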

Results

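Single-cell RNA sequencing was performed on dissociated mammary tumours of FVB mice carrying the MMTV-PyMT transgene, which drives the polyoma middle T oncogene in mammary epithelium. There were 2 libraries from mice aged 12 weeks and 2 from mice aged 15 weeks, each a droplet library of 3' tags with unique molecular identifiers (UMIs). The libraries held 33405883 UMIs in 2490 barcodes (12 weeks replicate 1), 36701749 in 4592 (12 weeks replicate 2), 4759920 in 1426 (15 weeks replicate 1) and 39537150 in 5875 (15 weeks replicate 2). After filtering, 1795, 2869, 1262 and 3870 cells remained, with medians of 12243, 8655, 2724 and 6848.5 UMIs per cell. The library 15 weeks replicate 1 was therefore the shallowest, and 1.40% of its barcodes had more than 15% mitochondrial UMIs, against 24.3%, 30.3% and 25.6% in the other libraries. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples.

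Cells fell into 8 named classes, of which epithelial-like cells, with the keratins Krt8 and Krt18 and the adhesion molecule Epcam among their markers, were the most numerous. Epithelial-like cells made up 66.9% ± 4.21 (SD, n = 2) of cells at 12 weeks and 68.6% ± 4.52 at 15 weeks, and macrophage/monocyte-like cells 13.7% ± 3.47 and 14.8% ± 7.81. Fibroblast-like cells made up 5.78% ± 3.09 and 3.50% ± 0.424, endothelial-like cells 4.61% ± 0.410 and 3.13% ± 0.173, and pericyte-like cells 0.436% ± 0.222 and 1.94% ± 1.18. T/NK cell-like cells (2.47% ± 1.32 and 1.79% ± 2.19), myoepithelial-like cells (2.38% ± 1.44 and 4.39% ± 5.55) and neutrophil-like cells (0.801% ± 0.443 and 0.724% ± 0.912) varied most between replicates for their size at 15 weeks. Clusters that no marker list named held 1.13% ± 0.592 of cells at 15 weeks, 1.87 percentage points less than at 12 weeks. No class differed by the exact two-sided permutation test, in which 2 libraries against 2 cannot give a p below 0.33. Endothelial-like cells (exact p = 0.333) and pericyte-like cells (exact p = 0.333) were the named classes whose libraries did not overlap between ages. Single shares had exact 95% binomial intervals that cover counting error only. For T/NK cell-like cells, 3 of 1262 cells in 15 weeks replicate 1 gave 0.238% (0.0490% to 0.693%), against 129 of 3870 or 3.33% (2.79% to 3.95%) in 15 weeks replicate 2. Without 15 weeks replicate 1 the difference between ages turned from -0.680 to 0.867 percentage points for T/NK cell-like cells, from 2.01 to -1.91 for myoepithelial-like cells, from 1.72 to -1.47 for epithelial-like cells and from -0.0767 to 0.568 for neutrophil-like cells. Without 12 weeks replicate 1 it turned to 0.252 (T/NK cell-like), -1.25 (epithelial-like), 0.236 (neutrophil-like) and, from 1.14, to -1.31 (macrophage/monocyte-like). That of macrophage/monocyte-like cells also turned to -4.38 without 15 weeks replicate 2.

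The study's title concerns suppression of type I interferon signalling within tumour cells after hypoxia. The comparison of ages in epithelial-like cells addresses how interferon and hypoxia genes stand in these cells as tumours age. Genes of the type I interferon response, the antiviral programme induced through the receptor Ifnar1 and Ifnar2, lay higher at 15 weeks in 44 of 45 tested members, with a median log2 fold change of 1.31. The antiviral effector Isg15 had 63.9 and 89.0 CPM at 12 weeks and 343 and 217 CPM at 15 weeks, a log2 fold change of 1.87 ± 0.35 (SE, n = 2 per age). Bst2, which tethers budding virus (2.20 ± 0.56), Oas2, which senses double-stranded RNA (2.52 ± 0.36), Lgals3bp (2.37 ± 0.31), Oasl2 (1.95 ± 0.28) and Ifit1 (1.68 ± 0.52) also lay higher in both 15-week libraries. Bst2 had 1.14 without 15 weeks replicate 1, and Ifit1 1.09 without 12 weeks replicate 1 and 2.64 without 12 weeks replicate 2. Camera with its preset correlation called the list (adjusted p = 4.93e-54), and adjusted p = 0.611 with an estimated correlation. None of the 45 members passed edgeR's test adjusted over all genes, and 22 did when adjusted over the list alone. The mean of the list over libraries, relative to the mean of the 4, was -0.90 and -0.28 log2 units at 12 weeks and 0.61 and 0.57 at 15 weeks.

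Transcription factors that carry the interferon signal had log2 fold changes of 1.31 ± 0.35 (Irf7), 0.71 ± 0.43 (Stat2) and 0.40 ± 0.30 (Irf9). Ifit3 had 1.34 ± 0.50, and 0.62 without 15 weeks replicate 2. Stat2 had 0.25 without 12 weeks replicate 1 and 1.36 without 12 weeks replicate 2, and Irf9 0.68 without 12 weeks replicate 2 and 0.16 without 15 weeks replicate 1. The receptor chain Ifnar1 had 0.13 ± 0.31 (-0.18 without 15 weeks replicate 1), and the 15 members of the list for interferon induction and receptors had a median of 0.09 (camera adjusted p = 0.922). For antigen presentation, B2m had 1.16 ± 0.50 and H2-K1 0.69 ± 0.48. Without 15 weeks replicate 2 they had 0.28 and -0.14. The MHC class I list, with a median of 0.33, was called by camera (adjusted p = 0.0481) and had adjusted p = 0.667 with an estimated correlation. Its median was 0.21 without 12 weeks replicate 2 and -0.15 without 15 weeks replicate 2, and the call was also lost without 12 weeks replicate 1 (median 0.37). The type II interferon list had a median of 0.50 (camera adjusted p = 0.00237, and adjusted p = 0.644 with an estimated correlation), and lost its call without 12 weeks replicate 2 (0.58) or 15 weeks replicate 2 (0.35).

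Hypoxia genes also lay higher at 15 weeks, in 26 of 38 members with a median log2 fold change of 0.50 (camera adjusted p = 2.29e-06, and adjusted p = 0.611 with an estimated correlation; no member passed over all genes and 5 did when adjusted over the list alone). The angiogenic factor Vegfa had a log2 fold change of 2.03 ± 0.64, with 8.80 and 5.90 CPM at 12 weeks and 47.8 and 13.6 CPM at 15 weeks. It had 0.86 without 15 weeks replicate 1, which thus carries much of the value. The mitochondrial protein Higd1a had 1.15 ± 0.24. The glucose transporter Slc2a1 (0.30 ± 0.38), Errfi1 (-0.24 ± 0.29) and the hypoxia-inducible factor subunit Hif1a (0.04 ± 0.23) had smaller values, and Slc2a1 had -0.33 without 15 weeks replicate 1. The glycolysis list had a median of 0.13 (camera adjusted p = 0.211) and the proliferation list 0.03 (camera adjusted p = 0.910). Genes with negative values and the smallest p, none of which passed, included the chemokine Ccl2 (-2.48 ± 0.33) and the milk protein gene Lalba (-1.78 ± 0.26). The others were the adhesion molecule Icam1 (-1.80 ± 0.29), Smr2 (-4.21 ± 0.70) and the transcription factor Maff (-1.64 ± 0.29). Smr2 also stands among the top genes of cluster 15, which drew 33 and 166 of its 210 cells from the 12-week libraries. Among the genes with positive values and the smallest p were Adm2 (3.74 ± 0.59) and Caskin2 (1.80 ± 0.30), which did not pass either. The NF-kB list had a median of -0.21 (camera adjusted p = 1.83e-05, and adjusted p = 0.651 with an estimated correlation), which was -1.20 without 15 weeks replicate 1 and 0.10 without 15 weeks replicate 2.

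No gene among 13390 passed an adjusted p of 0.05 in edgeR between ages in epithelial-like cells, while DESeq2 called 36. In edgeR 487 genes had an unadjusted p under 0.05. They make up a share under 0.05 of the genes, no more than without any difference between ages. Tested on simulated data of the same design, edgeR called 1.49% of genes changed 2-fold, 28.4% of those changed 4-fold and 74.2% of those changed 8-fold. Without 15 weeks replicate 1 edgeR called 8 genes, and without 15 weeks replicate 2 it called 2. Transcripts of stromal cells fell with age in the same sums (median -1.29, camera adjusted p = 5.84e-07, and adjusted p = 0.651 with an estimated correlation). That median was -0.04 without 12 weeks replicate 1, -1.94 without 12 weeks replicate 2 and -2.03 without 15 weeks replicate 2. Immune transcripts from other cells had a median of -0.63 (camera adjusted p = 0.00420, and adjusted p = 0.655 with an estimated correlation), which was 0.18 without 12 weeks replicate 1, -1.19 without 12 weeks replicate 2, -0.13 without 15 weeks replicate 1 and -2.68 without 15 weeks replicate 2. Clusters differed in the libraries they drew on. Cluster 3 drew 788 of its 825 cells from 15 weeks replicate 1, and clusters 4, 5 and 11 drew 616 of 746, 486 of 527 and 237 of 270 from 15 weeks replicate 2. Clusters 0 and 7 held 392 and 298 cells of 12 weeks replicate 1, and clusters 0 and 2 held 758 and 327 of 12 weeks replicate 2. Cluster 2 also held 484 cells of 15 weeks replicate 2. Without the clusters mostly of 1 library, the interferon median was 0.79 and the hypoxia median 0.14, and edgeR called 2 genes. That fit kept 1060 and 1842 epithelial-like cells at 12 weeks, but 112 of 906 in 15 weeks replicate 1 and 1177 of 2531 in 15 weeks replicate 2.

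**Figure D1:**
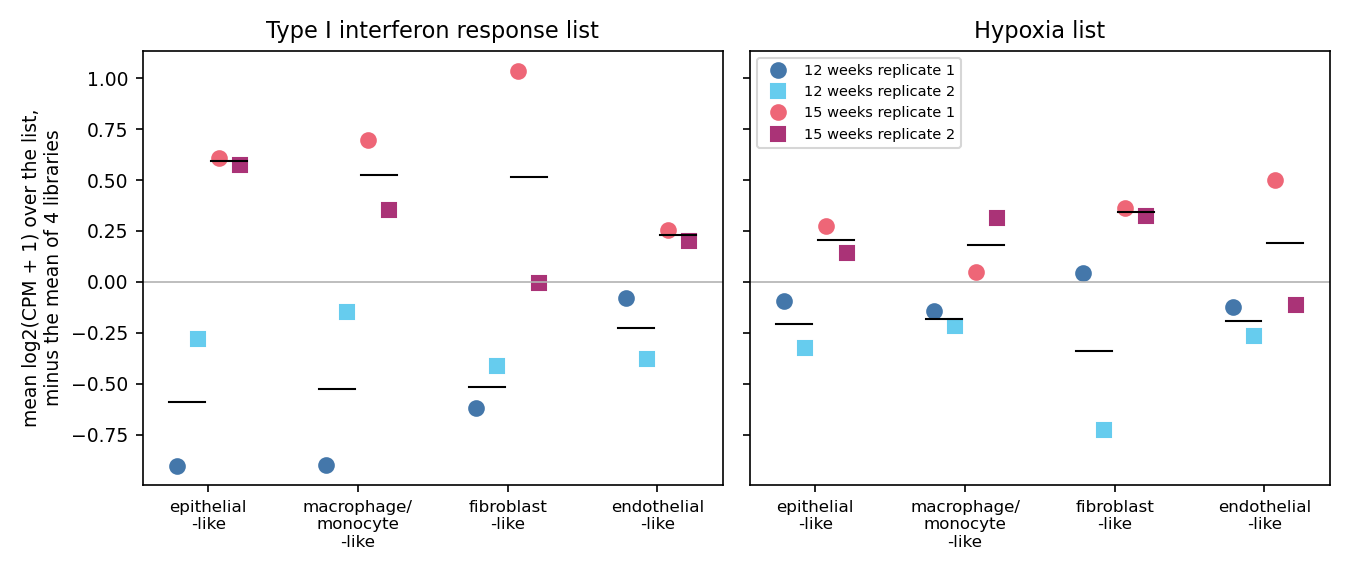
Mean log2(CPM + 1) over the type I interferon response list (left) and the hypoxia list (right) in 4 cell classes, minus the mean of the 4 libraries, with 1 point per library and a black bar at the mean of each age (n = 2). In epithelial-like cells the interferon list lies at -0.90 and -0.28 at 12 weeks and at 0.61 and 0.57 at 15 weeks, and both 15-week libraries lie above both 12-week libraries in all 4 classes.

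Epithelial-like cells of 15 weeks replicate 1 also stood apart along 2 chromosomes. Transcripts of 117 genes on chromosome 15 from position 3268547 to 77970813 lay 0.43 log2 units above the mean of the 4 libraries at the median, with 95 of them positive. Those of 75 genes from 80077791 to 101430313 of the same chromosome lay at -0.53, with 4 positive. Those of 127 genes on chromosome 11 from 102162497 to 120991330 lay at 0.48, with 104 positive. In the same order, epithelial-like cells lay at -0.17, 0.17 and -0.24 in 12 weeks replicate 1 and at -0.23, 0.12 and -0.34 in 12 weeks replicate 2. In 15 weeks replicate 2 they lay at -0.07, 0.25 and 0.01, each above both 12-week libraries. For the 75 genes of chromosome 15 this was opposite in direction to 15 weeks replicate 1. These parts were chosen after the windows were seen. Lgals3bp and Caskin2 lie inside that of chromosome 11, and Adm2 and Lalba inside the lowered part of chromosome 15. Macrophage/monocyte-like cells of the library had 0.08, -0.06 and 0.01 over the same parts. Of 229 windows of 40 genes, 15 lay beyond 0.3 in this library, against 1 in 12 weeks replicate 1, 4 in 12 weeks replicate 2 and 1 in 15 weeks replicate 2.

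**Figure D2:**
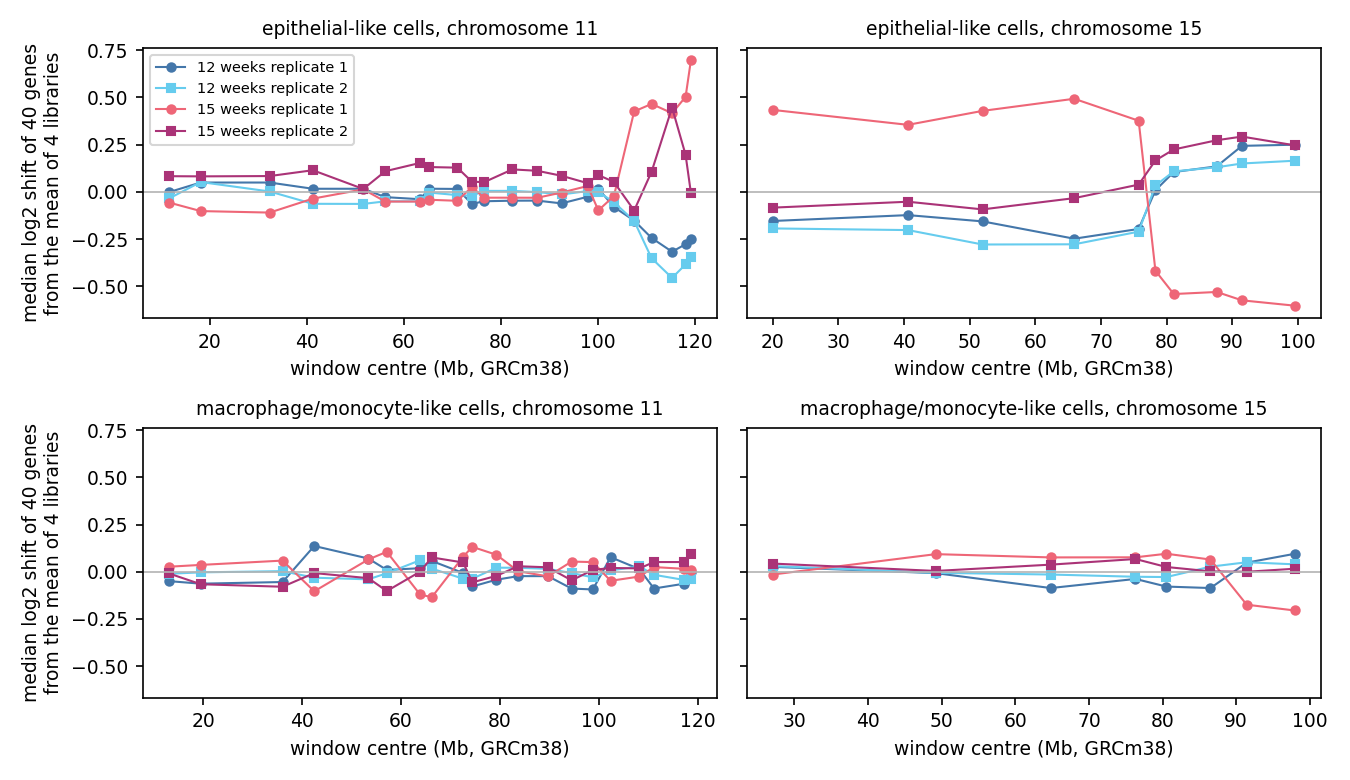
Median log2 shift of windows of 40 neighbouring genes from the mean of the 4 libraries, along chromosomes 11 (left) and 15 (right), in epithelial-like (top) and macrophage/monocyte-like cells (bottom). In epithelial-like cells of 15 weeks replicate 1, windows range from -0.60 to 0.70, and those beyond 0.3 lie on chromosomes 11 and 15.

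Macrophage/monocyte-like cells showed the same direction of interferon genes with age, together with lower transcripts for MHC class II. The type I interferon list had a median log2 fold change of 0.95 with 41 of 43 members positive (camera adjusted p = 1.12e-35, and adjusted p = 0.454 with an estimated correlation). None of these members passed over all genes and 17 did when adjusted over the list alone, among them Ifitm3, which restricts viral entry (1.03 ± 0.27, n = 2 per age), and Ifi27l2a (1.64 ± 0.38, and 1.05 without 15 weeks replicate 1). The MHC class II list, whose products present peptides to CD4 T cells, fell with a median of -1.02 and 8 of 9 members negative (camera adjusted p = 1.29e-10, and adjusted p = 0.454 with an estimated correlation; 0 passed over all genes and 5 when adjusted over the list alone). The invariant chain Cd74 had -1.02 ± 0.42, H2-Aa -1.42 ± 0.40 and H2-Ab1 -1.08 ± 0.36.

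Glycolysis genes had a median of 0.58 in macrophage/monocyte-like cells and 12 of 14 members positive (camera adjusted p = 4.68e-07, and adjusted p = 0.454 with an estimated correlation), including Gapdh (0.66 ± 0.27) and Ldha (0.71 ± 0.26). The libraries did not part by age on the mean of the list, which was -0.09 and -0.14 at 12 weeks and -0.16 and 0.40 at 15 weeks (exact permutation p = 1.00). The median was 0.46 without 15 weeks replicate 2. The hypoxia list rose with a median of 0.54 (camera adjusted p = 1.91e-09, and adjusted p = 0.454 with an estimated correlation). Hilpda, a lipid droplet protein, had 1.01 ± 0.25. The hypoxia median was 0.02 without 15 weeks replicate 2. By gene, edgeR called 4 of 9292. The acute-phase gene Saa2 fell by 3.45 ± 0.38 on the log2 scale (adjusted p = 0.0290) and Lalba fell by 3.02 ± 0.41 (adjusted p = 0.0496). The haemoglobin genes Hbb-bs (5.98 ± 0.75, adjusted p = 0.0431) and Hba-a1 (5.76 ± 0.77, adjusted p = 0.0495), named after their values were seen, rose from at most 1.95 CPM to between 9.92 and 86.2 CPM. Saa2 and Lalba also stand among the top genes of epithelial-like cluster 0. With genes of other classes left out, edgeR called 2 genes, both among these 4 and both higher, so neither Saa2 nor Lalba was called. Lalba and the casein gene Csn3 (-2.38 ± 0.41) are milk protein genes, and the epithelial transcripts fell in this class as a list, with a median of -0.48 (camera adjusted p = 9.89e-11, and adjusted p = 0.454 with an estimated correlation). That median was -0.25 without 12 weeks replicate 1, -0.92 without 12 weeks replicate 2, -0.19 without 15 weeks replicate 1 and -2.76 without 15 weeks replicate 2. The count of called genes was 29 without 12 weeks replicate 1, 51 without 12 weeks replicate 2, 14 without 15 weeks replicate 1 and 2 without 15 weeks replicate 2, where none of the 4 genes was called (Saa2 -3.16, Lalba -9.90). DESeq2 called Saa2 and Lalba only. The count was 0 with the lenient cell filter and at Leiden resolution 0.5, and with equal numbers of cells per library it was 3, none of them among these 4 genes.

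In fibroblast-like cells, Cxcl9, a chemokine induced by interferon gamma that attracts T cells, rose at 15 weeks from 2.88 and 3.24 CPM to 100 and 43.0 CPM, a log2 fold change of 4.16 ± 0.55 (n = 2 per age; edgeR adjusted p = 0.0337). The water channel Aqp2 rose (2.47 ± 0.33, adjusted p = 0.0337) and Aqp1, another water channel, fell by 3.54 ± 0.48 on the log2 scale (adjusted p = 0.0337). Tac1, which encodes the neuropeptide substance P, fell (adjusted p = 0.0258) from 216 counts over both 12-week libraries to 2 counts over both 15-week libraries, a ratio of 42.6 with a counting interval of 11.7 to 354. Aqp1 also stands among the top genes of endothelial-like cluster 8. With genes of other classes left out, edgeR called 7 genes, 6 higher and 1 lower. Of these 4 genes 3 were among them, so Tac1 and Aqp1 did not both stay called. Without 15 weeks replicate 2, Aqp2 (2.09), Tac1 (-9.23) and Aqp1 (-3.38) lost their calls. The proliferation list rose with a median of 0.96 and 20 of 22 members positive (camera adjusted p = 1.07e-13, and adjusted p = 0.551 with an estimated correlation; 6 members passed when adjusted over the list alone). Its member with the highest level, H2afz, had 0.21 ± 0.27, and the list median was 1.85 without 12 weeks replicate 2, 1.44 without 15 weeks replicate 1 and 0.10 with equal numbers of cells per library, where the call was lost.

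The type I interferon list rose in fibroblast-like cells with a median of 0.69 and 25 of 29 members positive (camera adjusted p = 4.58e-14, and adjusted p = 0.551 with an estimated correlation; 6 members passed when adjusted over the list alone), with Ifitm3 at 0.69 ± 0.28. Its median was 0.43 without 15 weeks replicate 1 and 1.43 without 15 weeks replicate 2. Cxcl10, a chemokine related to Cxcl9, had 483 CPM in 15 weeks replicate 1 and 5.16 CPM in 15 weeks replicate 2 (2.59 ± 1.31), and -2.43 without 15 weeks replicate 1. Glycolysis genes rose with a median of 0.57 (camera adjusted p = 1.50e-07, and adjusted p = 0.551 with an estimated correlation), Gapdh among them at 1.04 ± 0.27. The list median was 0.86 without 12 weeks replicate 1 and 0.33 without 12 weeks replicate 2. The hypoxia list rose with a median of 0.45 (camera adjusted p = 6.26e-10, and adjusted p = 0.551 with an estimated correlation). It had 0.77 without 12 weeks replicate 1 and -0.16 when each cell was thinned to 1000 UMIs. Immune transcripts from other cells fell, with a median of -1.09 (camera adjusted p = 6.83e-05, and adjusted p = 0.551 with an estimated correlation), -0.56 without 12 weeks replicate 1 and -6.66 without 15 weeks replicate 2. In all, edgeR called 4 of 8504 genes. The count was 18 without 12 weeks replicate 1, 35 without 12 weeks replicate 2, 158 without 15 weeks replicate 1 and 29 without 15 weeks replicate 2. It was 0 with cells thinned to 1000 UMIs, 0 with equal numbers of cells per library and 1, Tac1, with the lenient cell filter.

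In endothelial-like cells, genes that passed the test between ages included Angpt2 and cell cycle genes, which were higher at 15 weeks, and leukocyte adhesion molecules, which were lower. Angpt2 destabilises vessels as an antagonist of the receptor Tek. It rose from 36.4 and 26.8 CPM to 335 and 272 CPM, a log2 fold change of 3.23 ± 0.32 (n = 2 per age; edgeR adjusted p = 0.000673). The potassium channel subunit Kcne3 rose by 2.60 ± 0.32 (adjusted p = 0.00466). The cell cycle genes Ube2c (3.23 ± 0.47), Ccnb2 (2.97 ± 0.56), Pttg1 (2.42 ± 0.43) and Cdk1 (2.38 ± 0.37) rose. So did the antioxidant enzyme gene Gpx3 (2.40 ± 0.34), the glycolytic enzyme gene Tpi1 (1.58 ± 0.27) and the casein gene Csn1s2a (3.40 ± 0.64), with adjusted p values from 0.0135 to 0.0490. Csn1s2a is a milk protein gene that also stands among the top genes of epithelial-like cluster 3. In endothelial-like cells it had -0.12 with the strict cell filter, 5.31 and no call without 12 weeks replicate 1 and 2.48 and no call without 12 weeks replicate 2. It had 1.24 and no call without doublet removal and 1.58 and no call at Leiden resolution 0.5. Epithelial transcripts had a median of -0.30 there (camera adjusted p = 0.181). Slc38a1, an amino acid transporter, had 0 counts at 12 weeks and 17 at 15 weeks, which was at least 13.7-fold higher against a floor of 3 counts over both 12-week libraries (adjusted p = 0.0395). The neutrophil chemokine Cxcl1 fell by 1.97 ± 0.31 on the log2 scale. The leukocyte adhesion molecules Icam1 and Selp (P-selectin) fell by 1.81 ± 0.29 and 1.56 ± 0.28, with adjusted p values of these 3 genes from 0.0188 to 0.0387. No gene was called without 12 weeks replicate 1 or without 12 weeks replicate 2. Without 15 weeks replicate 2, most of the called genes were no longer called, among them Pttg1 (1.40), Cdk1 (2.02), Gpx3 (2.69), Tpi1 (1.54), Cxcl1 (-2.03), Icam1 (-1.96) and Selp (-1.66).

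By list, NF-kB genes fell in endothelial-like cells in 13 of 13 members with a median of -1.24 (camera adjusted p = 2.44e-13, and adjusted p = 0.275 with an estimated correlation; 2 members passed over all genes and 8 when adjusted over the list alone). The median was -2.03 without 15 weeks replicate 2. Immediate early genes, which tissue dissociation also induces, fell in 22 of 22 members with a median of -0.73 (camera adjusted p = 3.09e-12, and adjusted p = 0.275 with an estimated correlation; 0 passed over all genes and 13 when adjusted over the list alone), with Fos at -0.82 ± 0.25 and Junb at -0.87 ± 0.24. Nfkbia, the NF-kB inhibitor induced by the pathway, had -0.75 ± 0.25. Glycolysis genes rose with a median of 0.66 (camera adjusted p = 1.32e-08, and adjusted p = 0.308 with an estimated correlation), and 0.36 without 15 weeks replicate 1. The type I interferon list rose with a median of 0.42 and 27 of 33 members positive (camera adjusted p = 5.26e-07, and adjusted p = 0.275 with an estimated correlation; 4 members passed when adjusted over the list alone), with Bst2 at 0.74 ± 0.32. The proliferation list rose with a median of 0.93 (camera adjusted p = 3.83e-12, and adjusted p = 0.511 with an estimated correlation; 3 of 26 members passed over all genes), but had 0.24 and no call without 15 weeks replicate 2, -0.13 with cells thinned to 1000 UMIs and -0.12 with equal numbers of cells per library. The angiogenic list had a median of -0.15 (camera adjusted p = 0.513), and Angpt2 and Selp moved in opposite directions within it. In all, edgeR called 15 of 6646 genes, 11 higher and 4 lower. It called 0 without 12 weeks replicate 1 or without 12 weeks replicate 2, when 1 library stood for that age, 92 without 15 weeks replicate 1 and 4 without 15 weeks replicate 2. It called 3 with cells thinned to 1000 UMIs, 3 with the lenient cell filter, 1 without doublet removal, 1 with a replicate block, 6 at Leiden resolution 0.5 and 12 with equal numbers of cells per library.

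To compare epithelial-like cells by their level of hypoxia genes, those of each library were ranked by a hypoxia score. The 25% with the highest score were set against the 25% with the lowest. After thinning, the score rested on few UMIs per cell. Median scores by library were 0.0256 or 0.0513 in cells of low score and from 0.158 to 0.235 in cells of high score. The most abundant score gene was Errfi1, which the score of core hypoxia genes left out. Glycolysis genes, which were not in the score, rose in cells of high score, in 14 of 15 members with a median log2 fold change of 0.49 (camera adjusted p = 6.48e-07, and adjusted p = 0.278 with an estimated correlation; 8 members passed over all genes and 12 when adjusted over the list alone). Pgk1 (0.98 ± 0.21, n = 4 libraries), Aldoa (0.71 ± 0.16), Pkm (0.47 ± 0.12) and Hk2 (1.04 ± 0.24) were among them. At 12 weeks alone the glycolysis list had 0.23 and was not called (camera adjusted p = 0.0669). Proliferation genes fell in 20 of 20 members, with a median of -1.17 (camera adjusted p = 1.47e-24, and adjusted p = 0.0322 with an estimated correlation), and 17 passed over all genes. The thymidylate genes Tk1 (-2.38 ± 0.38) and Tyms (-1.63 ± 0.26), the replication genes Rrm2 (-1.73 ± 0.33) and Pclaf (-1.68 ± 0.22) and the mitotic genes Ccnb1 (-2.24 ± 0.36), Cdk1 (-1.59 ± 0.29), Pbk (-1.72 ± 0.30), Top2a (-1.53 ± 0.29) and Mki67 (-1.53 ± 0.35) all fell. Without 12 weeks replicate 2, Hk2 (1.16) and Pkm (0.49) lost their calls. Without 15 weeks replicate 2, Pgk1 (0.77), Hk2 (0.66), Pkm (0.38), Top2a (-1.49) and Mki67 (-1.48) lost theirs, as did Mki67 without 12 weeks replicate 1 (-1.26). Random lists matched on expression gave a proliferation median between -0.81 and 2.39 and a glycolysis median between -0.27 and 0.25.

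The NF-kB list rose in cells of high score with a median of 0.88 and 16 of 18 members positive (camera adjusted p = 1.96e-09, and adjusted p = 0.229 with an estimated correlation; 8 passed over all genes), including Tnfaip3 (1.79 ± 0.32), Nfkbia (1.04 ± 0.15) and Cxcl1 (1.14 ± 0.18). With a score of core hypoxia genes alone, an alternative chosen after seeing the data, its median was 0.20 and the call was lost, and Cxcl1 had -0.05. The immediate early list rose with a median of 0.68 (camera adjusted p = 5.08e-11, and adjusted p = 0.278 with an estimated correlation), with Ier3 at 1.16 ± 0.13. It had 0.44 without 15 weeks replicate 2. The basal keratin and progenitor list rose with a median of 0.59 (camera adjusted p = 5.21e-05, and adjusted p = 0.229 with an estimated correlation), through Krt17 (1.97 ± 0.34), Krt14 (1.00 ± 0.21) and Sox9 (0.60 ± 0.13). It had -0.09 when glycolysis genes were added to the score. The p53 list rose with a median of 0.49 (camera adjusted p = 0.000360, and adjusted p = 0.229 with an estimated correlation), led by the cyclin-dependent kinase inhibitor Cdkn1a (1.40 ± 0.18). The mesenchymal list rose with a median of 0.43 (camera adjusted p = 0.00373, and adjusted p = 0.229 with an estimated correlation), with S100a6 at 0.64 ± 0.12. It had 0.28 and no call with a score of core hypoxia genes and 0.13 and no call when glycolysis genes were added. The fibroblast matrix and contractile list rose by more, in 5 of 5 members with a median of 0.81 (camera adjusted p = 0.0428, and adjusted p = 0.278 with an estimated correlation). It had 0.48 and no call with unthinned counts and 0.42 and no call with the lenient cell filter. The highest medians of random lists were 0.881 for NF-kB (against 0.885), 0.668 for immediate early (against 0.684) and 0.520 for basal keratin genes. For p53 and mesenchymal genes they were 0.285 and 0.389, and for fibroblast matrix genes 0.717 over 48 random lists. The luminal keratins Krt8 (0.88 ± 0.11) and Krt18 (0.85 ± 0.10) and the claudin Cldn4 (1.28 ± 0.14) rose as well. Among the genes with the largest increases were the growth factor Hbegf (1.71 ± 0.20), the matricellular protein gene Ctgf (1.88 ± 0.29) and the AP-1 subunit Fosl1 (1.68 ± 0.24). Others were the urokinase receptor Plaur (1.72 ± 0.30), Maff (1.81 ± 0.18), Fhl2 (1.79 ± 0.41), Ovol1 (1.66 ± 0.30) and Emp1 (1.66 ± 0.16). Of the genes reported for this comparison, 20 lost their call with a score of core hypoxia genes, 1 reversed and 19 kept their side of the threshold. When glycolysis genes were added to the score, 17 lost their call, 2 reversed and 18 kept their side. Without 12 weeks replicate 2, Tnfaip3 (1.42), Ovol1 (1.33) and Krt14 (0.86) lost their calls, and without 15 weeks replicate 2 Sox9 (0.54) did.

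Oxidative phosphorylation genes encoded in the nucleus fell slightly with the score, in 40 of 41 members with a median of -0.23 (camera adjusted p = 9.15e-07, and adjusted p = 0.229 with an estimated correlation). Mitochondrially encoded genes fell with a median of -0.37 (camera adjusted p = 5.21e-05, and adjusted p = 0.501 with an estimated correlation). Random lists gave the latter a median of -0.19, from -0.44 to 0.0019, and 5 of 100 were as extreme. It had -0.20 and no call with the strict cell filter and -0.15 and no call with unthinned counts. Milk and alveolar genes fell with a median of -0.29 (camera adjusted p = 0.000603, and adjusted p = 0.416 with an estimated correlation), through Wap (-1.17 ± 0.18) and Csn3 (-0.47 ± 0.14). Random lists gave them a median of -0.16, and 20 of 100 were as extreme. Within ages, milk and alveolar genes had 0.06 at 12 weeks with 10 of 16 members positive (camera adjusted p = 0.712). At 15 weeks they had -0.69 with 2 of 16 positive (camera adjusted p = 7.99e-09), so the fall was seen at 15 weeks only. Over both ages they had -0.23 and no call with unthinned counts, and 0.02 and no call when glycolysis genes were added to the score. Their median was -0.47 without 12 weeks replicate 1, -0.16 without 15 weeks replicate 1 and -0.05 without 15 weeks replicate 2, and Csn3 lost its call without 12 weeks replicate 2 (-0.59), 15 weeks replicate 1 (-0.40) or 15 weeks replicate 2 (-0.28). Scgb2b27, a secretoglobin gene, fell by 1.92 ± 0.24 on the log2 scale.

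Over both ages together, the type I interferon list did not pass in cells of high against low score, with a median of 0.17 and 20 of 30 members positive (camera adjusted p = 0.0949, and adjusted p = 0.870 with an estimated correlation). Of 100 random lists, 3 were as extreme. Within ages the list had -0.06 at 12 weeks (camera adjusted p = 0.960) and 0.26 at 15 weeks (camera adjusted p = 0.00168). The list was called without 12 weeks replicate 2 (0.27) and had 0.0036 without 15 weeks replicate 1. The exonuclease gene Isg20 rose (1.20 ± 0.32), a call that was lost without 12 weeks replicate 1 (1.15) or 15 weeks replicate 2 (1.27). The values of Isg15 (0.51 ± 0.17), Ifit1 (0.58 ± 0.26), Irf7 (0.44 ± 0.17), Irf9 (0.45 ± 0.24), Bst2 (0.21 ± 0.15), Ifnar1 (-0.51 ± 0.32), B2m (0.08 ± 0.15), H2-K1 (0.06 ± 0.12) and Hif1a (0.16 ± 0.22) did not pass. The MHC class I list had a median of 0.03 (camera adjusted p = 0.897).

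In all, edgeR called 474 of 6466 genes between cells of high and low score, 338 higher and 136 lower, with the library as a block. It called 179 without 12 weeks replicate 2 and 239 without 15 weeks replicate 2. It called 148 with glycolysis genes added to the score, 76 of them among the 474, and 47 with a score of core hypoxia genes, 39 of them among the 474. The median of 100 random lists, matched to the whole score list, was 78.5. The score is a continuous measure, so the groups are ranges and not cell types, and in 12 weeks replicate 1, 496 of 1113 scored cells lay within 0.05 of the lower limit. Medians of immune and of stromal transcripts from other cells were equal in both groups of cells, at 1 UMI per cell in 12 weeks replicate 1 and 0 in the other libraries, counts too low to show small differences. Cells of high and low score with a UMI of the stromal transcripts made up 56.1% and 61.9% in 12 weeks replicate 1, 34.4% and 35.5% in 12 weeks replicate 2, 15.2% and 19.9% in 15 weeks replicate 1 and 30.8% and 32.9% in 15 weeks replicate 2. Median mitochondrial shares of cells of high and low score were 4.15% and 5.17% in 12 weeks replicate 1, 4.17% and 5.85% in 12 weeks replicate 2, 2.97% and 2.90% in 15 weeks replicate 1 and 5.13% and 5.67% in 15 weeks replicate 2. The largest cluster among cells of high and low score was 0 and 2 in 12 weeks replicate 2 and 4 and 2 in 15 weeks replicate 2, and the same for both groups in the other libraries. Cluster 2 had a median of 4623.5 UMIs and, among its top genes, Gm26917, Gm42418 and Lars2, which are often high in cells of low RNA quality. It held 128 of 465 and 145 of 590 cells of low score in the 2 libraries. Lars2 fell with the score (-1.50 ± 0.22), while Gm42418 (-0.54 ± 0.22) and Gm26917 (-0.25 ± 0.28) did not pass. Differences in RNA quality between the groups are therefore not ruled out. Before thinning, cells of high and low score had medians of 16406.5 and 12056 UMIs in 12 weeks replicate 1, 13238 and 9364 in 12 weeks replicate 2, 3856 and 4236 in 15 weeks replicate 1 and 10580.5 and 8242.5 in 15 weeks replicate 2.

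The difference between cells of high and low score itself differed with age for 8 of 6466 genes in edgeR's interaction test. The glycolytic enzyme genes Pgk1 (1.40 ± 0.23, adjusted p = 0.0268) and Gapdh (1.06 ± 0.18, adjusted p = 0.0330) rose more from cells of low to cells of high score at 15 than at 12 weeks. So did the cytokine gene Mif (1.13 ± 0.17, adjusted p = 0.0199). The scores themselves also lay further apart at 15 weeks, which the test did not adjust for. Median scores of cells of low and high score were 0.0513 and 0.2015 in 12 weeks replicate 1 and 0.0256 and 0.1582 in 12 weeks replicate 2. They were 0.0513 and 0.2351 in 15 weeks replicate 1 and 0.0256 and 0.1877 in 15 weeks replicate 2. In 15 weeks replicate 1 Pgk1 had 347 CPM in cells of low and 1208.96 CPM in cells of high score, and in 12 weeks replicate 1 it had 204 and 232 CPM. The secreted proteins Saa1 (-1.57 ± 0.22, adjusted p = 0.0110), Lrg1 (-1.34 ± 0.22, adjusted p = 0.0268), osteopontin Spp1 (-1.21 ± 0.16, adjusted p = 0.0110) and Csn3 (-0.72 ± 0.13, adjusted p = 0.0359) had interaction values below 0, and mt-Co1, of the mitochondrial genome, had 0.82 ± 0.14 (adjusted p = 0.0331). The glycolysis list had a median of 0.23 at 12 weeks (camera adjusted p = 0.0669) and 0.83 at 15 weeks (camera adjusted p = 2.14e-19). The type I interferon list had -0.06 at 12 weeks (camera adjusted p = 0.960) and 0.26 at 15 weeks (camera adjusted p = 0.00168). These within-age p-values used the preset correlation only. The interaction median was 0.66 for glycolysis (camera adjusted p = 1.80e-11, and adjusted p = 0.368 with an estimated correlation) and 0.34 for interferon (camera adjusted p = 0.00819, and adjusted p = 0.998 with an estimated correlation). The interferon value was 0.62 without 12 weeks replicate 1, -0.03 without 12 weeks replicate 2, 0.22 without 15 weeks replicate 1 and 0.67 without 15 weeks replicate 2. The count of genes was 2 without 12 weeks replicate 1, 0 without 12 weeks replicate 2, 79 without 15 weeks replicate 1 and 91 without 15 weeks replicate 2, while DESeq2 called 0 and 387 genes had an unadjusted p under 0.05.

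Epithelial-like cells were set against macrophage/monocyte-like cells of the same libraries to place their interferon genes beside those of an immune class. The type I interferon list had a median log2 difference of -0.33 in epithelial-like relative to macrophage/monocyte-like cells, with 6 members higher and 20 lower of 45 (camera adjusted p = 0.0635, and adjusted p = 0.427 with an estimated correlation), and was called without 12 weeks replicate 1 (-0.33). Slfn2 (-3.26 ± 0.28, n = 4 libraries), Slfn5 (-3.36 ± 0.31) and Trim30a (-3.43 ± 0.35) were lower, as was Bst2 (-0.96 ± 0.21). Ifitm3 was higher (0.48 ± 0.19), a call lost without 12 weeks replicate 1 (0.54), 12 weeks replicate 2 (0.54) or 15 weeks replicate 2 (0.28). The receptor chains Ifnar1 (-3.07 ± 0.22) and Ifnar2 (-1.96 ± 0.14) and the transcription factor Irf5 (-8.20 ± 0.22) were lower, and the induction and receptor list had a median of -1.25 (camera adjusted p = 0.00149, and adjusted p = 0.427 with an estimated correlation). Irf8, a factor of the macrophage lineage, had -8.34 ± 0.31.

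For antigen presentation, the MHC class I list had a median of -0.63 in epithelial-like cells (camera adjusted p = 0.000231, and adjusted p = 0.427 with an estimated correlation), with H2-D1 at -2.02 ± 0.19, B2m at -2.39 ± 0.25 and H2-K1 at -0.96 ± 0.18. It lost its call without 15 weeks replicate 1 (-0.67). MHC class II genes were far lower, with a median of -7.13 (camera adjusted p = 3.37e-07, and adjusted p = 0.414 with an estimated correlation), H2-Aa at -9.46 ± 0.32 and Cd74 at -10.28 ± 0.42. The hypoxia list went both ways, with 12 members higher and 14 lower of 37 and a median of 0.11 (camera adjusted p = 0.953). The carbonic anhydrase Car12 (4.06 ± 0.20) and Errfi1 (2.32 ± 0.18) were higher in epithelial-like cells and the lactate transporter Slc16a3 (-5.29 ± 0.26) lower. Immune transcripts of the other-cell list had a median of -9.12. In all, edgeR called 6485 of 10737 genes, 3352 higher and 3133 lower in epithelial-like cells.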

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

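Chosen after the results were seen were the tests on macrophage levels, on members on other chromosomes, without clusters mostly of 1 library, with a score of core hypoxia genes, of the list mean by permutation and of swapped sums. So was the estimated correlation for the lists of this part. The fits without a library, with thinned cells, with random lists and within clusters were planned, but the bounds they were held to were set after the results were seen. The genes and lists here stand out because the difference between cells of high and low hypoxia score itself differed between 12 and 15 weeks in a test of that difference. Pgk1 (1.40), Gapdh (1.06) and the cytokine gene Mif (1.13) had higher values at 15 weeks, as had mt-Co1 (0.82). Saa1 (-1.57), Lrg1 (-1.34), Spp1 (-1.21) and Csn3 (-0.72), which encode secreted proteins, had lower values. Scores of cells of high and low score also lay further apart at 15 weeks, which the test did not adjust for. None of the 8 genes passed without 12 weeks replicate 2 (Pgk1 1.45, Gapdh 0.97, Mif 1.22, mt-Co1 0.81, Saa1 -1.47, Lrg1 -1.19, Spp1 -0.99, Csn3 -0.67), and without 12 weeks replicate 1 Spp1 alone did (-1.43).

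Among the lists, glycolysis (0.66), the type I interferon response (0.34), mitochondrially encoded genes (0.35) and ribosomal proteins (0.24) had interaction medians above 0. Milk and alveolar genes (-0.56) and NF-kB genes (-0.39) had medians below 0. Adjusted p with an estimated correlation was 0.368 for glycolysis and NF-kB, 0.998 for interferon, 0.843 for mitochondrially encoded genes and ribosomal proteins and 0.791 for milk and alveolar genes. The mitochondrial median was 0.59 without 15 weeks replicate 2, the milk median -0.35 without 12 weeks replicate 1 and the NF-kB median -0.63 without 12 weeks replicate 1. The interferon median was -0.03 without 12 weeks replicate 2.

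Among the results of the report, the higher interferon genes at 15 weeks in epithelial-like cells were weighed first. RNA from macrophages in the same droplets is argued against by immune transcripts, which lay at a median of -9.12 relative to macrophage/monocyte-like cells, while the interferon list lay at -0.33. Some members of that immune list, such as C1qa and Lyz2, are also markers that named the classes. A single library and depth are argued against as the whole cause by the list's medians of 0.98 (the lowest without a library) and 1.21 (cells thinned to 1000 UMIs). Clusters mostly of 1 library are argued against as the whole cause by a median of 0.79 without them, for the cells that remained. That fit kept 112 of 906 epithelial-like cells of 15 weeks replicate 1 and 1177 of 2531 of 15 weeks replicate 2. Copies of the list members on chromosomes 11 and 15 are argued against as the whole cause by the median of 1.31 over the 38 members on other chromosomes. Effects of other genes on chromosomes 11 and 15 on these members were not tested. Spread between single libraries or animals and the age of the mice cannot be told apart, since 2 libraries against 2 give an exact permutation p of 0.333.

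For the 474 genes that differed with the hypoxia score, 3 of 100 random lists of matched expression gave as many genes, and 180 of the genes also passed when cells were ranked within clusters. These values argue against any list of such expression, and against cluster membership, as the whole cause for the whole score list. The random lists were not matched on correlation among their genes, so other lists of correlated genes were not tested. A score of core hypoxia genes gave 47 genes, under the random median of 78.5, and random lists were not drawn for it, so how far the 474 genes rest on core hypoxia genes stays open. The 8 ways of swapping high and low sums within libraries are too few for a share under 0.05: the real one, the 1 with as many genes, gave 474 and the highest other gave 1. The same holds for epithelial-like against macrophage/monocyte-like cells, where the real one gave 6485 genes and the highest other 0, so that 1 of 8 had as many. Lower RNA quality of cells of low score was not tested as a cause and stays open. No biological explanation of the score genes was tested.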

How the results depend on the processing

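Leaving out clusters mostly of 1 library, the score of core hypoxia genes and the estimated correlation for the score were chosen after seeing the data. Of the gene values, 1630 kept their direction and side of the threshold, 239 no longer passed, 32 newly passed and 23 reversed. Of the list values, 828 kept both, 229 no longer passed, 14 newly passed and 32 reversed. Where a value changed, the cause was not tested, except that leaving out a library leaves fewer samples and the lenient filter left more cells unnamed.

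With DESeq2, counts of genes were 36 (epithelial-like), 2 (macrophage/monocyte-like), 13 (fibroblast-like), 159 (hypoxia score) and 0 (interaction). With fry, and with an estimated correlation, calls were lost at unchanged medians for interferon in epithelial-like (1.31), macrophage/monocyte-like (0.95), fibroblast-like (0.69) and endothelial-like cells (0.42), for hypoxia in epithelial-like cells (0.50) and for glycolysis by score (0.49). With fry, interferon in epithelial-like against macrophage/monocyte-like cells was called (-0.33). Without the low-count filter, counts were 74 (macrophage/monocyte-like), 130 (fibroblast-like), 142 (endothelial-like) and 27 (interaction), and interferon was called by score (0.20) and in epithelial-like against macrophage/monocyte-like cells (-0.26).

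The labels do not say what equal replicate numbers share, so they were not taken as pairs. Deviations of equal numbers correlated across genes at 0.0537, 0.0778, 0.105 and 0.104 in the 4 classes, over 2 pairs. With a replicate block, counts were 18 (macrophage/monocyte-like), 40 (fibroblast-like) and 1 (endothelial-like).

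With cells thinned to 1000 UMIs, counts were 8 (macrophage/monocyte-like), 0 (fibroblast-like) and 3 (endothelial-like). Reversed were, in epithelial-like cells, the macrophage state list (0.10), Irf9 (-0.032), Ifnar1 (-0.20) and Hif1a (-0.42), hypoxia in fibroblast-like (-0.16) and endothelial-like cells (-0.012) and proliferation in endothelial-like cells (-0.13). With equal numbers of cells the fibroblast-like count was 0 and endothelial proliferation -0.12. Without clusters mostly of 1 library, the epithelial-like count was 2, and the macrophage state list (0.16), immune transcripts (0.083), Slc2a1 (-0.37) and Hif1a (-0.00148) reversed. With genes of other classes left out, counts were 2 (macrophage/monocyte-like) and 7 (fibroblast-like), and in epithelial-like cells the macrophage state (0.13) and inflammatory fibroblast lists (0.051) reversed.

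With the lenient filter, counts were 0 (macrophage/monocyte-like), 1 (fibroblast-like) and 3 (endothelial-like). Basal keratins in macrophage/monocyte-like cells (0.047), Ifnar1 (0.00325) by score, and differences in share of epithelial-like (-6.31), neutrophil-like (0.272), unnamed (5.26) and T/NK cell-like cells (0.0364) reversed. With this filter, a cluster of 920 cells, 798 of them of 15 weeks replicate 2, led on epithelial markers but stayed unnamed. Unnamed cells made up 24.5% of that library, against 1.55% with the main filter, so the epithelial-like and unnamed shares changed in part through cluster naming. With the strict filter, the fibroblast-like count was 9, and Csn1s2a in endothelial-like cells (-0.12), Bst2 (-0.13) and B2m (-0.078) by score and the macrophage/monocyte-like share (-2.43) reversed. Macrophage/monocyte-like cells were not run with it, with too few cells in 15 weeks replicate 1. Without doublet removal, the endothelial-like count was 1, and basal keratins in macrophage/monocyte-like cells (0.076), B2m (-0.053) by score and shares of macrophage/monocyte-like (-0.134) and neutrophil-like cells (0.0505) reversed. At Leiden resolution 0.5, counts were 0 (macrophage/monocyte-like) and 6 (endothelial-like).

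For the hypoxia score, unthinned counts gave 2087 genes, where depth differs between the groups, and Ifit1 -0.47. Without Errfi1 there were 269 genes, with interferon called (0.18). Ranking within clusters gave 201 genes and B2m -0.061. With glycolysis genes in the score there were 148 genes, with interferon called (0.14). Milk genes (0.016), basal keratins (-0.091), fibroblast matrix genes (-0.24), Krt17 (-0.091) and Krt14 (-0.12) reversed. Core hypoxia genes gave 47 genes, and ribosomal proteins (0.024) and Cxcl1 (-0.052) reversed. Random lists gave a median of 78.5 genes.

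Without each library in turn, counts ranged from 0 to 8 (epithelial-like), 2 to 51 (macrophage/monocyte-like), 18 to 158 (fibroblast-like), 0 to 92 (endothelial-like), 179 to 457 (score) and 0 to 91 (interaction). In epithelial-like cells, ranges were -0.15 to 0.37 (MHC class I), -1.20 to 0.10 (NF-kB), -0.035 to 0.39 (ribosomal proteins), -1.59 to 0.011 (macrophage state), -2.01 to 0.18 (fibroblast matrix), -2.68 to 0.18 (immune transcripts), -0.14 to 1.18 (H2-K1), -0.18 to 0.40 (Ifnar1), -0.33 to 0.73 (Slc2a1) and -0.057 to 0.11 (Hif1a). In macrophage/monocyte-like cells they were -0.96 to 0.032 (mitochondrially encoded), -0.36 to 1.00 (proliferation), -1.07 to 0.12 (basal keratins) and -0.031 to 0.56 (ribosomal proteins). In fibroblast-like cells they were -1.14 to 0.13 (mitochondrially encoded), -2.35 to 0.48 (milk), -3.18 to 0.10 (epithelial transcripts), -2.43 to 4.05 (Cxcl10) and -0.024 to 0.34 (H2afz), and in endothelial-like cells -1.23 to 0.10 (mitochondrially encoded). By score they were 0.0036 to 0.27 (interferon), -0.10 to 0.27 (B2m) and -0.11 to 0.36 (Hif1a). Interferon ranged from -0.025 to 0.67 in the interaction and from -0.52 to -0.26 in epithelial-like against macrophage/monocyte-like cells. Differences in share ranged from -1.47 to 4.92 (epithelial-like), -4.38 to 6.66 (macrophage/monocyte-like), -2.23 to 0.867 (T/NK cell-like), -1.91 to 5.94 (myoepithelial-like) and -0.722 to 0.568 (neutrophil-like). Depth limits 15 weeks replicate 1 most, with a median of 2724 UMIs per cell.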

Other observations

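Unfolded protein and integrated stress genes, which report on load in the endoplasmic reticulum, fell with age in macrophage/monocyte-like cells. Their median log2 fold change was -0.40 with 14 of 20 members negative (camera adjusted p = 0.00135, and adjusted p = 0.454 with an estimated correlation). NF-kB genes fell in the same class with a median of -0.28 (camera adjusted p = 0.00115, and adjusted p = 0.454 with an estimated correlation). They lost that call without 12 weeks replicate 2 (-0.22) or 15 weeks replicate 2 (-0.16). Stromal transcripts from other cells fell there as well, in 9 of 10 members (camera adjusted p = 0.00135, and adjusted p = 0.674 with an estimated correlation). Their median was -0.25 without 12 weeks replicate 1, -1.81 without 12 weeks replicate 2 and -1.57 without 15 weeks replicate 2. In fibroblast-like cells the inflammatory fibroblast list rose with a median of 0.65 (camera adjusted p = 0.0121, and adjusted p = 0.551 with an estimated correlation), and lost its call without 12 weeks replicate 2 (0.49) or 15 weeks replicate 2 (0.19).

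The tests of the next pattern were chosen after it was seen. Epithelial-like cells of 15 weeks replicate 1 had neighbouring genes shifted together on 2 of the 20 chromosomes scanned, 11 and 15. A difference between libraries that acts on every cell, such as depth or GC content, is argued against by macrophage/monocyte-like cells of the same library, whose largest shift relative to that of epithelial-like cells over the 3 parts was 0.0799 (against 0.43). Gains and losses of gene copies in the tumour cells of this library would produce shifts next to each other on few chromosomes, as seen here, and this remains a hypothesis, since DNA was not analysed here. The same end of chromosome 11 lay at 0.45 in 1 window of 15 weeks replicate 2. Over the whole part of chromosome 11 that library lay at 0.01, against -0.24 and -0.34 in the 12-week libraries. Over the raised part of chromosome 15 it lay at -0.07, against -0.17 and -0.23.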
